A study of Mus musculus with 25 samples.

How the data were processed

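The samples were hepatocytes from perfused and dissociated mouse liver, of which 500000 sorted cells per sample were lysed for RNA, per the labels' protocols. Libraries were made with a kit that reads the 3′ ends of polyadenylated transcripts (QuantSeq 3′ mRNA-Seq FWD), so a gene's count depends on its 3′ end and not on its length. Reads were checked with FastQC, trimmed with cutadapt and aligned with STAR 2.6.1d to mm10 (GRCm38), per the submitters' processing notes. The counting tool, the gene annotation and the use of strand are not given in the sources used here, so antisense and overlapping genes are uncertain, as are paralogs such as the Mup, Cyp2c, Serpina1 and Saa genes. The authors deposited a single table of counts, whole numbers per gene and library with no normalization, with 37117 gene symbols and 25 columns. The kit and the labels name no molecular identifiers, so intervals on counts cover counting error only.

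Columns were matched to samples by name and grouped by the labels. Gene coordinates came from GENCODE release M21 (GRCm38), in which 36339 symbols, and 12742 of the genes tested, matched exactly 1 gene. Totals ranged from 8107539 to 16515330 counts per library, so 1 count was worth 0.036 to 0.14 CPM with TMM scaling. Replicates were compared by chi-square tests of their counts over genes. The lowest statistic per degree of freedom was 8.29 and the lowest correlation of log values between replicates 0.956, so no pair appeared to be 1 library deposited again.

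Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), which left 12970. Libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 25 libraries together with robust estimation (common dispersion 0.0425), so that the 7 groups share an estimate of the spread. Contrasts were tested with glmQLFTest, and p-values were adjusted by Benjamini-Hochberg over the genes of a contrast, with 0.05 as threshold. A standard error is the log2 fold change divided by the root of the F statistic. Fold changes use edgeR's prior count of 0.125. The contrasts were ApoYap Dox against ApoYap ctrl (Yap induction), Lats1/2 KO against Lats1/2 flox ctrl (Lats1/2 knockout), BL/6 Dox and BL/6 AAV-Cre against BL/6 ctrl, the first less the third (net of doxycycline), the second less the fourth (net of AAV-Cre), the second less the first, and each untreated strain against BL/6 ctrl. For named genes with 1 to 3 counts in a group, a ratio of scaled counts is given with an exact binomial 95% interval.

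The groups, contrasts, 37 gene lists, rule for named genes and most alternatives were fixed before the data were examined. The lists came from general knowledge of liver biology and not from these samples. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 37 lists of a contrast, with an estimated correlation and fry as alternatives. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. Members were also adjusted over the list alone. The named genes were the 6 higher and 6 lower genes with the largest fold change among those called, with an average log2 CPM of at least 2 and no overlap between treated and control libraries, for Yap induction and the knockout. For the other contrasts the number was 3 each way, without the overlap condition for differences of contrasts. Up to 4 members of each list with the smallest p, and Yap1, Lats1, Lats2, Ccn1, Ccn2, Ankrd1, Afp, Sox9, Alb and Cyp7a1, could be named too. Predicted genes, pseudogenes and Y-linked genes were skipped. The result for 1 of these genes is not reported here.

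The alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE scaling, total counts alone, scaling without the 50 most abundant genes, no filter, a filter of 10 CPM in 3 libraries, only the compared groups in the fit, the replicate number as a block, an adjusted p under 0.01, a log2 fold change of at least 1, a test against a fold of 1.5, and leaving out each library in turn. Leaving out BL/6 Dox 1 and 2 together and counting without marker genes were added after the data were seen.

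Calls shared by contrasts with common controls were set beside 10 simulations with unchanged groups and a split of the controls. Calls were also counted for all 35 splits of the libraries of a contrast of 2 groups, and for 50 drawn splits, the real one included, in differences of contrasts.

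The tests were tried on simulated counts with the library sizes and dispersions of the real data and the mean of the untreated groups for every gene. In each contrast 100 of 12970 genes were changed by a fold of 2 and 100 by a fold of 4, beside a list of 30 genes raised by a fold of 1.5. Of these, edgeR recovered 49% and 73% for Yap induction, 56% and 81% for the knockout, 55% and 80% for doxycycline alone and 53% and 76% for AAV-Cre alone. For net of doxycycline it recovered 33% and 71%, for net of AAV-Cre 37% and 60%, and for the knockout less Yap induction 33% and 72%. Between 4 and 9 unchanged genes were called in each of these runs. The real data called 67.0% of genes for Yap induction and 38.0% for the knockout. So many changes were not simulated, so the runs do not test the scaling in these contrasts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.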

Results

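RNA was measured at the 3′ ends of transcripts in hepatocytes sorted from mouse liver, in 25 libraries that fall into 7 groups. YAP is a transcriptional coactivator, and the Hippo kinases LATS1 and LATS2 keep it inactive by phosphorylation. ApoYap mice carry a doxycycline-controlled human YAP transgene driven in hepatocytes, and were sampled untreated (n = 4) and after 1 week of doxycycline (n = 3). Mice with floxed Lats1 and Lats2 were sampled untreated (n = 4) and 1 week after an adeno-associated virus carrying a hepatocyte-restricted Cre recombinase, which deletes both genes (n = 3). C57BL/6 mice, called BL/6 below, were sampled untreated (n = 4), after 1 week of doxycycline (n = 4) and 24 hours after the same virus (n = 3). The doxycycline water held 0.2 mg/ml of the drug and 2.5% sucrose. Totals ran from 8107539 to 16515330 counts per library, and the counts of replicates of a group differed by more than sampling noise in every pair. The labels do not say whether replicates are separate animals, so each p-value measures the spread between these samples. They also give no sex, age or batch.

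The libraries of both ways of raising YAP activity lay apart from all others. On principal component 1, which held 64.9% of the variance of log2 CPM, the 3 ApoYap Dox libraries lay between 165.1 and 186.7 and the 3 Lats1/2 KO libraries between 47.97 and 101.7. The 19 other libraries lay between −72.6 and −20.7. Component 2 held 5.96% of the variance and separated Lats1/2 KO (39.9 to 54.1) from ApoYap Dox (−35.5 to −21.7).

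**Figure D1:**
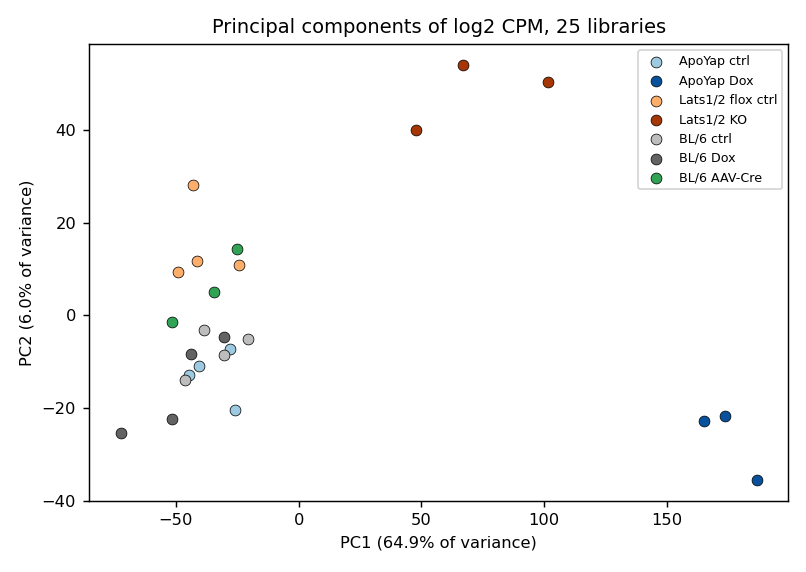
Principal components 1 and 2 of log2 CPM, in arbitrary units, with each point a library and each colour a group. The 3 ApoYap Dox libraries lie at 165.1 or above on component 1 and the 3 Lats1/2 KO libraries between 47.97 and 101.7, both apart from the untreated and BL/6 libraries.

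The targeted genes were examined in every library. Lats1 (chromosome 10, 7681214 to 7716460, GRCm38) was counted at 5.10, 4.79 and 2.97 CPM in the 3 knockout libraries and at 12.3 to 14.9 CPM in their 4 controls, and fell by 1.67 on the log2 scale (SE 0.23, adjusted p = 4.1e-06). Lats2 (chromosome 14, 57689662 to 57758388) stood at 7.70, 17.8 and 10.5 CPM in the knockout libraries against 12.9 to 13.7 CPM in the controls, a log2 difference of −0.13 (adjusted p = 0.65). Without Lats1/2 KO 2 that difference was −0.52 with adjusted p = 0.044. It turned to 0.098 without Lats1/2 KO 1 (adjusted p = 0.76) and to 0.36 with total counts alone (0.19). The library reads 3′ ends and the labels do not give the deleted exons, so a Lats2 tag outside the deleted part checks nothing. Mouse Yap1 (chromosome 9, 7931999 to 8004596) was counted at 24.8, 20.2 and 16.99 CPM in ApoYap Dox against 40.97 to 46.9 CPM in ApoYap ctrl, and fell by 1.05 (SE 0.12, adjusted p = 2.3e-08). Scaled by total counts alone the Yap1 difference was −0.13 and was not called. The transgene is human and the labels do not give its 3′ end, so the mouse Yap1 count does not measure it. In the knockout Yap1 fell by 0.33 (adjusted p = 0.026), a call lost without Lats1/2 KO 1 (−0.27, adjusted p = 0.13), without Lats1/2 KO 2 (−0.31, 0.099) and without Lats1/2 flox ctrl 2 (−0.31, 0.063), and also with RLE scaling (adjusted p = 0.069) and DESeq2 (0.071). With total counts alone the Yap1 difference in the knockout was 0.14. Neither doxycycline nor the virus in BL/6 mice gave a call for Yap1 (−0.05 and 0.05), Lats1 (0.28 and 0.35) or Lats2 (0.00 and 0.56).

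Induction of human YAP for 1 week was followed by a large rise of YAP target genes. Ccn2 (chromosome 10, 24595442 to 24598683), a secreted matricellular protein and a standard YAP target, went from 1.69 ± 0.63 CPM (SD, n = 4) to 173.2 ± 11.3 CPM (SD, n = 3), a log2 fold change of 6.69 (SE 0.46, adjusted p = 1.3e-10). Ccn1 (chromosome 3, 145646976 to 145649981), a related protein, went from 9.53 ± 1.91 to 170.4 ± 16.5 CPM, a log2 fold change of 4.16 (SE 0.31, adjusted p = 1.9e-10). Ankrd1 (chromosome 19, 36111961 to 36120099) rose by 4.89 and Amotl2, which binds YAP, by 3.16. Of the 20 members measured in the YAP/TAZ target signature, 15 rose, 1 fell (Nt5e, named after its values were seen) and 4 were not called, with the same numbers adjusted over the list alone. The list median was 1.97 (camera adjusted p = 5.4e-05; adjusted p = 0.060 with an estimated correlation). Endothelial and macrophage markers rose by medians of 2.81 and 5.61 in the same libraries, so the rise of this list is not assigned to hepatocytes alone. Lats2, itself a YAP target, rose by 1.502. Among 26 Hippo pathway components 16 rose and 4 fell, also when adjusted over the list alone, with a median of 1.03 (adjusted p = 0.0072; adjusted p = 0.18 with an estimated correlation). Ajuba, a scaffold that inhibits LATS, rose by 2.81.

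**Figure D2:**
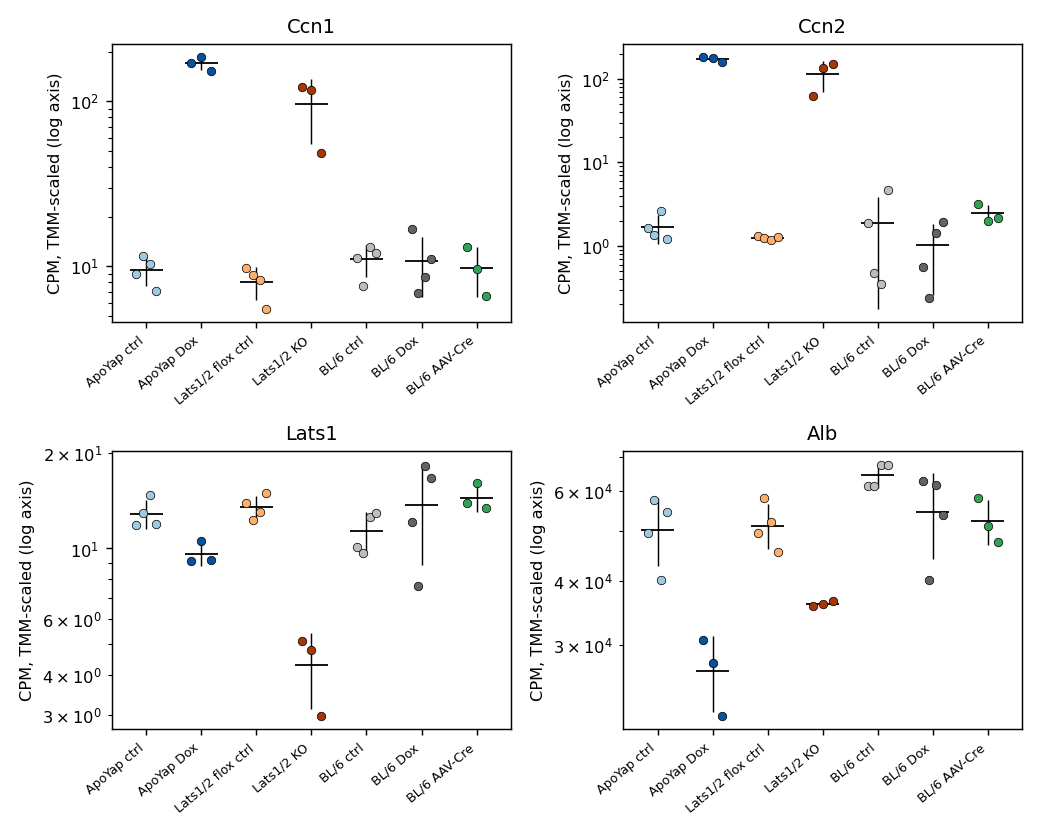
CPM with TMM scaling on a log axis for Ccn1, Ccn2, Lats1 and Alb, with 1 point per library, the group mean as a line and ± 1 SD as a bar; a lower bar that would pass below 0 is stopped above 0. Ccn2 reached 160.6 CPM or more in each of the 3 ApoYap Dox libraries and 62.5 CPM or more in each Lats1/2 KO library, against at most 4.73 CPM elsewhere.

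The 6 genes with the largest rises under the fixed rule were Apela, Gpc3, Krt4, Lrtm2, Dusp2 and Mmp9. Apela, which encodes a ligand of the apelin receptor, gave 1 count over the 4 control libraries and 2843 over the 3 treated ones, a scaled ratio of 1842 with a 95% counting interval of 330.4 to 72793. Krt4, a keratin, had 3 counts in the controls and a ratio of 333.1 (113.8 to 1617). Gpc3, a glypican of fetal liver, rose by 8.76 (SE 0.34), Lrtm2 by 8.12, Dusp2, a phosphatase of MAP kinases, by 7.83 and Mmp9, a gelatinase, by 7.69. Macrophage and neutrophil markers rose by medians of 5.61 and 5.90 in the same libraries, so the rises of Dusp2 and Mmp9 are not assigned to hepatocytes. The 6 largest falls were those of Hsd3b5 (−8.71), a steroid dehydrogenase of male liver, Mup2 (−8.56), Cyp2c40 (−8.01), Elovl3 (−8.00), a fatty acid elongase, Mup15 (−7.96) and Mup17 (−7.94). The Mup and Cyp2c families hold near-identical copies, so the split of reads between their members is uncertain.

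Genes of cell division rose with YAP. Of 37 G2/M phase genes 36 rose and 1 was not called, with a median log2 fold change of 4.30 (camera adjusted p = 4.4e-12; adjusted p = 0.15 with an estimated correlation). Mki67, a marker of cycling cells, rose by 5.70. Of 37 S phase genes 30 rose, 1 fell (Mcm10, named after its values were seen) and 6 were not called, with a median of 2.30 (adjusted p = 7.7e-09; adjusted p = 0.060 with an estimated correlation). Mcm6, a subunit of the replicative helicase, rose by 3.35 and E2f1, a cell cycle transcription factor, by 2.74. Adjusted over the list alone, the numbers called higher were 36 and 31. Among 15 fetal liver genes 11 rose and none fell, also when adjusted over the list alone, with a median of 1.90 (adjusted p = 1.2e-04; adjusted p = 0.060 with an estimated correlation). In that list Scd2 rose by 4.16 and Afp, the fetal albumin homologue, by 1.90, while Igf2bp1, with 1 count in the controls, had a ratio of 230.7 (41.1 to 9137). Macrophage and endothelial markers rose by medians of 5.61 and 2.81 in the same libraries, so the rises of the lists in this paragraph are not assigned to hepatocytes.

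The actin cytoskeleton and adhesion list, to which Anxa5 (2.52) and Tln1 (2.16) belong, had 33 of 36 members higher and 1 lower (S100a10, named after its values were seen). Its median was 2.13 (adjusted p = 1.9e-11; adjusted p = 0.060 with an estimated correlation), and 33 were higher and 2 lower adjusted over the list alone. Among 23 genes of extracellular matrix and TGF beta ligands 18 rose and 2 fell, also adjusted over the list alone, with a median of 2.96 (adjusted p = 0.0010; adjusted p = 0.27 with an estimated correlation), and this call was lost with total counts alone (adjusted p = 0.051). Of the stellate cell markers 10 of 20 rose in the same libraries and endothelial markers rose by a median of 2.81, so the actin, adhesion and matrix genes are not assigned to hepatocytes. Of 11 cholangiocyte and progenitor markers 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 1.97 (adjusted p = 0.035; adjusted p = 0.27 with an estimated correlation; 0.40 with total counts alone). Lgals3 rose by 6.24 and Spp1, or osteopontin, by 5.398; macrophages express both, and macrophage markers rose by a median of 5.61 in the same libraries, so these 2 rises are not assigned to hepatocytes. Sox9, a transcription factor of bile duct cells, stood at 36.4 ± 6.402 and 34.4 ± 6.80 CPM, a log2 difference of −0.08 (adjusted p = 0.84). Under total counts alone the Sox9 difference was 0.84 and was called (adjusted p = 0.018).

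Genes of hepatocyte function fell. All 38 genes of the urea cycle and amino acid catabolism fell, by a median of 2.72 on the log2 scale (camera adjusted p = 1.7e-26; adjusted p = 0.044 with an estimated correlation). Arg1, the last enzyme of the urea cycle, fell by 3.15 and Uroc1, an enzyme of histidine breakdown, by 3.90. All 25 secreted plasma proteins fell, with a median of −1.89, among them Apoa2 (−5.45) and Ttr (−3.73), as did 27 of 30 complement and coagulation factors, with a median of −1.98 and F7 at −3.73. The adjusted p of these lists was 1.8e-16 and 9.2e-20, and 0.044 for each with an estimated correlation. Alb (chromosome 5, 90460897 to 90476602), the most abundant plasma protein, went from 50402 ± 7647 to 26687 ± 4528 CPM and fell by 0.92 (SE 0.16, adjusted p = 2.3e-05), while total counts alone gave a log2 difference of 0.00087 for Alb. All 24 genes of cholesterol synthesis and uptake fell, with a median of −2.09 and Fdps at −3.20 (adjusted p = 2.1e-13; 0.044 with an estimated correlation). All 23 genes of fatty acid and triglyceride synthesis fell, with a median of −2.90 and Fasn, the fatty acid synthase, at −4.22 (adjusted p = 8.8e-12; adjusted p = 0.060 with an estimated correlation). Adjusted over the list alone, the numbers lower were 38, 25, 27, 24 and 23 in these 5 lists.

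Bile acid, cytochrome P450 and zonation genes moved with them. Of 24 genes of bile acid synthesis and transport 21 fell and 2 rose (Slco1a4 and Abcc4, named after their values were seen), with a median of −2.29 (adjusted p = 2.3e-11; 0.044 with an estimated correlation). Slc10a1, the bile acid uptake carrier, fell by 5.43, Abcb11, the bile salt export pump, by 3.30 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 2.73 (SE 0.82, adjusted p = 0.0067). Of 30 cytochrome P450 and xenobiotic enzymes 27 fell and 1 rose, with a median of −3.14 (adjusted p = 3.0e-13; adjusted p = 0.055 with an estimated correlation). Pericentral genes fell in 18 of 21 cases with a median of −3.89 (adjusted p = 2.2e-07; adjusted p = 0.15 with an estimated correlation), among them Cyp2e1 at −7.23. Periportal genes fell in 19 of 20 cases with a median of −2.79 (adjusted p = 2.1e-13; 0.013 with an estimated correlation), among them Cyp2f2 at −3.80, so both zonal lists fell. Of 22 hepatocyte transcription factors 16 fell and 1 rose, with a median of −1.27 (adjusted p = 8.6e-04; adjusted p = 0.060 with an estimated correlation); Hnf4a fell by 1.27 and Nr0b2 fell by 6.01. Of 15 male-biased liver genes 13 fell, with a median of −5.33 (adjusted p = 5.5e-11, or 0.055 with an estimated correlation). The labels give no sex, so this fall and that of Hsd3b5 are not separated from a difference of sex between the groups. Of 29 genes of fatty acid oxidation and PPAR alpha targets 24 fell and 4 rose, with a median of −1.46 (adjusted p = 1.3e-06; adjusted p = 0.15 with an estimated correlation). Of 29 acute phase genes 18 fell and 2 rose, with a median of −1.28 (adjusted p = 0.0012; adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone, these counts were the same except for a further P450 gene called higher, 2 in all.

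Mitochondrially encoded mRNAs made up 14.6 ± 1.47% of counts in ApoYap ctrl and 6.37 ± 0.87% in ApoYap Dox. All 8 of them measured fell, also adjusted over the list alone, with a median of −2.08 and mt-Co1 at −2.18 (adjusted p = 6.6e-07; 0.044 with an estimated correlation). Of 40 cytosolic ribosomal protein genes 38 rose and 2 were not called, also adjusted over the list alone, with a median of 0.66 and Rpl32 at 0.88 (adjusted p = 1.8e-05; adjusted p = 0.27 with an estimated correlation). Glycolysis genes went both ways, 7 higher and 9 lower of 21 in both adjustments (adjusted p = 0.92), with Hk2, a hexokinase of growing cells, at 6.08 and Pkm, the non-hepatic pyruvate kinase, at 5.02; macrophages express both, so these 2 rises are not assigned to hepatocytes. The glycolysis median was −0.26 while the mean was 0.94 and camera pointed upward, and the median was 0.66 with total counts alone. Interferon response genes rose in 19 of 34 cases and fell in 3 (20 and 3 adjusted over the list alone), with a median of 0.73 (adjusted p = 0.031; adjusted p = 0.62 with an estimated correlation). Immediate early and dissociation genes rose in 18 of 28 cases and fell in 2, with a median of 1.72 (adjusted p = 0.013; adjusted p = 0.50 with an estimated correlation), and ATF4 and amino acid stress genes rose in 14 of 25 cases and fell in 2, with a median of 1.34 (adjusted p = 0.046; adjusted p = 0.15 with an estimated correlation), both with the same counts adjusted over the list alone. These last 3 list calls were lost with total counts alone, and the first 2 lists include genes that macrophages express.

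Markers of other liver cells rose in the same sorted samples. The 21 markers of Kupffer cells and macrophages all rose, by a median of 5.61 (camera adjusted p = 8.8e-12; adjusted p = 0.15 with an estimated correlation), with Timd4 at 6.24 and Cd68 at 5.61. Their summed counts went from 200.2 ± 74.7 unscaled CPM, meaning relative to the library total without TMM (SD, n = 4), to 19131 ± 6527 (SD, n = 3). Of 21 sinusoidal endothelial markers 20 rose (21 adjusted over the list alone), with a median of 2.81 and Tie1 at 2.81 (adjusted p = 2.1e-05; adjusted p = 0.35 with an estimated correlation), and their sum went from 266.0 ± 99.3 to 3283 ± 1121 unscaled CPM. The 6 neutrophil markers measured all rose, with a median of 5.90 (adjusted p = 0.0040; adjusted p = 0.15 with an estimated correlation; 0.11 with total counts alone), from 5.07 ± 2.84 to 497.9 ± 234.9 unscaled CPM. S100a8 among them, with 3 counts in the controls, had a ratio of 77.8 (26.4 to 378.8). Stellate cell and fibroblast markers, 10 of 20 higher, were not called as a list (adjusted p = 0.083), at 112.6 ± 39.7 and 469.2 ± 120.2 unscaled CPM. For T, NK and B cell markers the sums were 3.78 ± 0.80 and 24.6 ± 10.2 unscaled CPM, with 4 of 6 higher (adjusted p = 0.19). Adjusted over the list alone, the numbers higher were 21, 6, 10 and 4 for macrophages, neutrophils, stellate cells and lymphocytes.

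**Figure D3:**
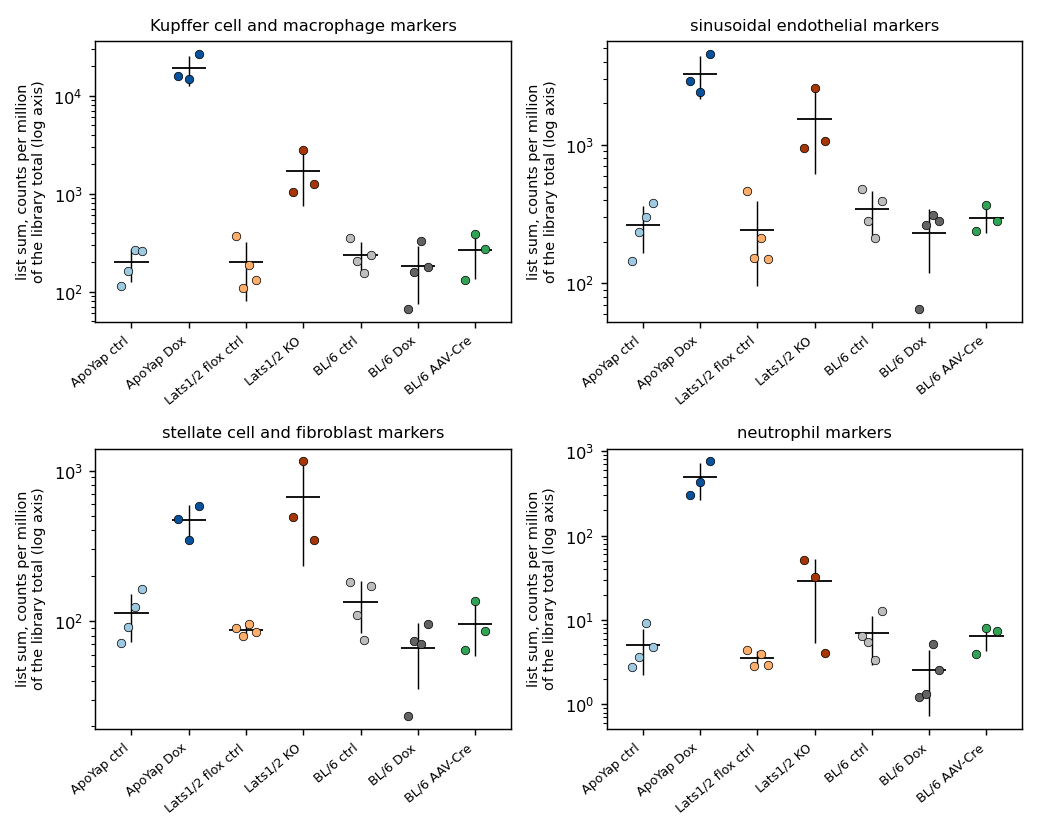
Summed counts of 4 marker lists in unscaled CPM, on log axes, with 1 point per library, the group mean as a line and ± 1 SD as a bar; a lower bar that would pass below 0 is stopped above 0. Macrophage marker sums lie between 14760 and 26633 unscaled CPM in ApoYap Dox and between 1048 and 2826 in Lats1/2 KO, and at most at 385.9 in the other groups.

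Over all 12970 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4536 genes higher and 4148 lower after Yap induction. Without the 79 marker genes of other cell types measured, these counts were 4474 and 4147. Such counts, here and below, leave out only the listed genes. They cannot show how many of the other calls come from RNA of other cells. The scaling sets the balance of the directions: total counts alone gave 8613 higher and 1638 lower, 84.0% higher instead of 52.2%, and raised the median of all genes by 0.92, while RLE scaling raised it by 0.11. Values here are relative to the TMM scale. The 8 lists that camera did not call were stellate cell, T, NK and B cell, p53 target (14 higher, 5 lower of 22, adjusted p = 0.16), circadian clock (3 and 8 of 18, 0.25, with a median of −0.58 that was 0.33 with total counts alone), NRF2 target (7 and 8 of 24, 0.74, with a median of 0.06 and camera downward), female-biased (3 and 2 of 5, 0.89), erythroid (1 and 1 of 5, 0.89) and glycolysis genes.

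YAP target genes were higher in the Lats1/2 knockout too. Ccn2 went from 1.26 ± 0.05 CPM (SD, n = 4) to 115.6 ± 46.5 CPM (SD, n = 3), a log2 fold change of 6.51 (SE 0.48, adjusted p = 8.2e-09). Ccn1 went from 8.09 ± 1.83 to 96.2 ± 41.1 CPM, a log2 fold change of 3.57 (SE 0.31, adjusted p = 4.2e-08). Ankrd1 was at 0.26 ± 0.17 and 2.03 ± 1.39 CPM and rose by 2.94 (SE 0.78, adjusted p = 0.0047), with 0.42 CPM in Lats1/2 KO 3. Amotl2 rose by 2.77 and Ajuba by 4.74. Stellate cell, endothelial and macrophage markers rose by medians of 2.61, 2.29 and 2.78 in the same libraries, so the rises of YAP targets are not assigned to hepatocytes alone. Of the 20 YAP/TAZ targets 14 rose and none fell (15 and 0 adjusted over the list alone), with a median of 2.40 (camera adjusted p = 3.6e-09; 0.030 with an estimated correlation). Of 26 Hippo pathway components 10 rose and 3 fell (Lats1, Yap1 and Vgll4, the last named after its values were seen), also adjusted over the list alone, with a median of 0.31 (adjusted p = 0.0075; adjusted p = 0.19 with an estimated correlation).

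The 6 largest rises in the knockout were those of Krt4, Ccn2, Gpc3 (6.43), Lrtm2 (5.94), Itgam and Cdc20 (5.55). Krt4 had 2 counts in the controls and a ratio of 147.8 with a 95% counting interval of 40.6 to 1225. Itgam, an integrin of myeloid cells, had 2 counts in the controls and a ratio of 69.2 (18.9 to 576.2). The 6 largest falls were those of Mup9 (−5.11), Cyp4a14 (−3.94), a fatty acid hydroxylase, Mmd2 (−3.88), Mup17 (−3.67), Apoa4 (−3.62), an apolipoprotein, and Mup15 (−3.55). The Cyp4a14 call (adjusted p = 0.0097) was lost without Lats1/2 flox ctrl 3 (−2.30, adjusted p = 0.067) and without Lats1/2 KO 2 (−3.68, 0.052). The Mup17 call was lost without Lats1/2 KO 1 (−3.14, adjusted p = 0.051) and without Lats1/2 KO 2 (−3.14, 0.060). Without Lats1/2 KO 3 the falls of Mup17 and Mup15 reached −6.81 and −5.47.

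Cell division genes rose in the knockout as a group. Of 37 G2/M phase genes 35 rose (36 adjusted over the list alone), by a median of 4.62 (camera adjusted p = 1.7e-44; 0.013 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, rose by 5.55, Ndc80, a kinetochore protein, by 4.92 and Cenpa, the centromeric histone, by 3.62. Of 37 S phase genes 30 rose and 1 fell (Mcm10 again), also adjusted over the list alone, with a median of 1.70 (adjusted p = 2.0e-17; 0.013 with an estimated correlation); Uhrf1 rose by 4.91 and Mcm6 by 3.33. Of 22 p53 targets 13 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 1.05 (adjusted p = 1.8e-04; adjusted p = 0.11 with an estimated correlation). Mdm2, the negative regulator of p53, rose by 1.23 and Ccng1 by 0.92. Net of the virus the p53 list was not called (median 0.19, adjusted p = 0.96). Of 36 actin cytoskeleton and adhesion genes 29 rose, also adjusted over the list alone, with a median of 1.23 (adjusted p = 6.9e-17; adjusted p = 0.051 with an estimated correlation), Anxa5 at 2.67 and Myh9, non-muscle myosin, at 1.78. Extracellular matrix genes rose in 18 of 23 cases and fell in 1 (19 and 1 adjusted over the list alone), with a median of 2.30 (adjusted p = 1.6e-07; adjusted p = 0.15 with an estimated correlation). Stellate cell and fibroblast markers, whose cells make matrix, rose by a median of 2.61 in the same libraries, so the matrix genes are not assigned to hepatocytes. Macrophage and endothelial markers rose there by medians of 2.78 and 2.29, so the cell division, actin and adhesion genes are not assigned to hepatocytes either.

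Among 15 fetal liver genes 8 rose and none fell, also adjusted over the list alone, with a median of 1.38 (adjusted p = 6.1e-04; adjusted p = 0.13 with an estimated correlation), including Scd2 (2.40), Cdkn1c (1.46) and Afp (1.38, SE 0.39). Of 11 cholangiocyte and progenitor markers 8 rose, also adjusted over the list alone, with a median of 2.62 (adjusted p = 0.0018; adjusted p = 0.15 with an estimated correlation), including Anxa3 (3.27) and Spp1 (3.24). Macrophage markers rose by a median of 2.78 in the same libraries, so Spp1 is not assigned to progenitor cells here either. Sox9 went from 54.7 ± 17.9 to 131.8 ± 74.7 CPM and rose by 1.26 (SE 0.32, adjusted p = 0.0035), a call lost without Lats1/2 KO 1 (0.75, adjusted p = 0.059) and with only the 2 compared groups in the fit (adjusted p = 0.058).

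Hepatocyte genes fell in the knockout as well. Of 38 genes of the urea cycle and amino acid catabolism 32 fell (35 adjusted over the list alone), by a median of 0.998 on the log2 scale (camera adjusted p = 6.9e-17; adjusted p = 0.086 with an estimated correlation), with Asl at −1.77 and Arg1 at −1.36. Of 25 secreted plasma proteins 22 fell (23), with a median of −0.73 (adjusted p = 6.5e-10; adjusted p = 0.13 with an estimated correlation), Ttr at −1.64 and Ahsg at −1.10. Alb went from 51312 ± 5234 to 36116 ± 424.2 CPM and fell by 0.51 (SE 0.16, adjusted p = 0.015), and with total counts alone its log2 difference was −0.04. Complement and coagulation factors fell in 22 of 30 cases and rose in 2 (27 and 2), with a median of −0.67 (adjusted p = 3.1e-08; adjusted p = 0.16 with an estimated correlation) and F7 at −1.19. Fatty acid and triglyceride synthesis fell in 17 of 23 genes (18), with a median of −1.22 (adjusted p = 1.2e-08; adjusted p = 0.13 with an estimated correlation) and Fasn at −1.52. Cholesterol synthesis and uptake fell in 18 of 24 genes (18), with a median of −0.67 (adjusted p = 8.8e-07; adjusted p = 0.16 with an estimated correlation). The counts in brackets are those adjusted over the list alone. With total counts alone the medians were −0.55 for the urea cycle list, −0.27 for plasma proteins and −0.21 for complement and coagulation factors. They were −0.77 for fatty acid and −0.20 for cholesterol synthesis, and camera still called each list lower. Whether dilution by RNA of other cells gave the falls of hepatocyte genes in the knockout, here and in the next paragraphs, was not tested.

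Bile acid genes fell in 12 of 24 cases and rose in 2, also adjusted over the list alone, with a median of −0.81 (adjusted p = 7.3e-06; adjusted p = 0.15 with an estimated correlation). Slc10a1 fell by 1.76 and Abcb11 by 1.11. Cyp7a1 was at 99.8 ± 45.7 and 35.6 ± 47.8 CPM, a log2 difference of −1.47 that was not called (adjusted p = 0.13), and it was called without Lats1/2 KO 3 (−3.60, adjusted p = 6.8e-04). Pericentral genes fell in 11 of 21 cases, also adjusted over the list alone, with a median of −1.20 (adjusted p = 1.7e-05; adjusted p = 0.20 with an estimated correlation). Glul, glutamine synthetase, fell by 2.61 and Lgr5, a Wnt target at the central vein, by 2.67. Periportal genes fell in 12 of 20 cases (16 adjusted over the list alone), with a median of −0.86 (adjusted p = 4.0e-08; 0.046 with an estimated correlation). Cytochrome P450 and xenobiotic enzymes fell in 19 of 30 cases and rose in 3, with a median of −0.72 (adjusted p = 9.4e-05; adjusted p = 0.22 with an estimated correlation) and Ephx2 at −1.36. Hepatocyte transcription factors fell in 9 of 22 cases, with a median of −0.59 (adjusted p = 4.5e-04; adjusted p = 0.086 with an estimated correlation) and Cebpa at −1.04. Male-biased genes fell in 10 of 15 cases and rose in 1, with a median of −0.95 (adjusted p = 2.5e-04; adjusted p = 0.20 with an estimated correlation). Of these last 3 lists 19, 10 and 10 members were lower adjusted over the list alone. As the labels give no sex, the fall of male-biased genes is not separated from a difference of sex here either.

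Of 29 genes of fatty acid oxidation and PPAR alpha targets 17 fell and 4 rose in the knockout, with a median of −0.51 (camera adjusted p = 0.0063; adjusted p = 0.37 with an estimated correlation). Cd36, a fatty acid transporter, rose by 2.63; macrophages and endothelial cells express it, and their markers rose by medians of 2.78 and 2.29, so this rise is not assigned to hepatocytes. Acute phase genes fell in 11 of 29 cases and rose in 1, with a median of −0.55 (adjusted p = 0.012; adjusted p = 0.51 with an estimated correlation) and Saa1, whose reads can be shared with its paralogs, at −4.44. Mitochondrially encoded mRNAs, 12.5 ± 0.56% of counts in the controls and 11.1 ± 0.52% in the knockout, fell in 6 of 8 cases, with a median of −0.67 (adjusted p = 0.0016; adjusted p = 0.16 with an estimated correlation). NRF2 targets rose in 9 of 24 cases and fell in 2, with a median of 0.51 (adjusted p = 0.029; adjusted p = 0.20 with an estimated correlation). Adjusted over the list alone, 17 genes of fatty acid oxidation, 12 acute phase genes and 7 mitochondrial mRNAs were lower and 9 NRF2 targets higher. With total counts alone the medians of fatty acid oxidation, acute phase genes and mitochondrial mRNAs were −0.068, −0.083 and −0.20, with each list still called lower. Cytosolic ribosomal protein genes were not called as a list (0 higher, 2 lower of 40, adjusted p = 0.57), with a median of −0.05 that was 0.42 with total counts alone. Interferon response genes rose in 11 of 34 cases and fell in 3 (13 and 3 adjusted over the list alone), with a median of 0.59 (adjusted p = 0.046; adjusted p = 0.69 with an estimated correlation), a call lost with total counts alone and net of the virus (median −0.13, adjusted p = 0.46). Not called were immediate early genes (11 higher and 5 lower of 28, adjusted p = 0.16), ATF4 targets (6 and 3 of 25, 0.70), clock genes (0 and 6 of 18, 0.062), female-biased genes (0 and 1 of 5, 0.32), erythroid markers (1 and 1 of 5, 0.68) and glycolysis (4 and 3 of 21, 0.84). The glycolysis median was −0.04 with a mean of 0.54 and camera upward. With total counts alone the medians of glycolysis, clock and female-biased genes were 0.43, 0.13 and 0.33 where that of all genes was 0.44, so their sign turned by the shift of all genes; the last 2 lists, below that median, were called.

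Markers of other liver cells also rose in the knockout samples. Macrophage markers rose in 18 of 21 cases, by a median of 2.78 (camera adjusted p = 3.3e-12; adjusted p = 0.16 with an estimated correlation), with Marco at 4.90 and Cd68 at 2.98, and their sum went from 199.8 ± 119.6 to 1712 ± 970.6 unscaled CPM. All 21 endothelial markers rose, by a median of 2.29 (adjusted p = 6.5e-10; adjusted p = 0.19 with an estimated correlation), with Pecam1 at 2.79 and Tie1 at 2.44, and their sum went from 244.7 ± 149.1 to 1542 ± 922.1 unscaled CPM. Stellate cell and fibroblast markers rose in 19 of 20 cases, by a median of 2.61 (adjusted p = 4.2e-08; adjusted p = 0.17 with an estimated correlation), with Lum at 2.84, from 87.6 ± 6.84 to 662.4 ± 429.4 unscaled CPM. Lats1/2 KO 2 had the highest sums of these 3 lists, at 2826, 2605 and 1151 unscaled CPM, and without it the means were 1155, 1011 and 417.9. Neutrophil markers were higher in 4 of 6 cases and not called as a list (adjusted p = 0.052), at 3.54 ± 0.79 and 29.3 ± 23.9 unscaled CPM, with a median of 2.48 that was 1.91 with Retnlg, at 0 counts in 1 group, set to its bound of 3 counts over the group. T, NK and B cell markers had no member called (adjusted p = 0.70), at 4.31 ± 3.25 and 5.39 ± 2.73 unscaled CPM. Adjusted over the list alone, the numbers higher were 20, 21, 19, 5 and 0 in these 5 lists.

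The knockout gave 2668 genes higher and 2258 lower, and 2605 and 2257 without the marker genes of other cell types. Total counts alone gave 5781 higher and 572 lower, 91.0% higher instead of 54.2%, and raised the median of all genes by 0.47. Without Lats1/2 KO 2 only 1391 genes were called lower, and with only the 2 compared groups in the fit 1449 were.

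**Figure D4:**
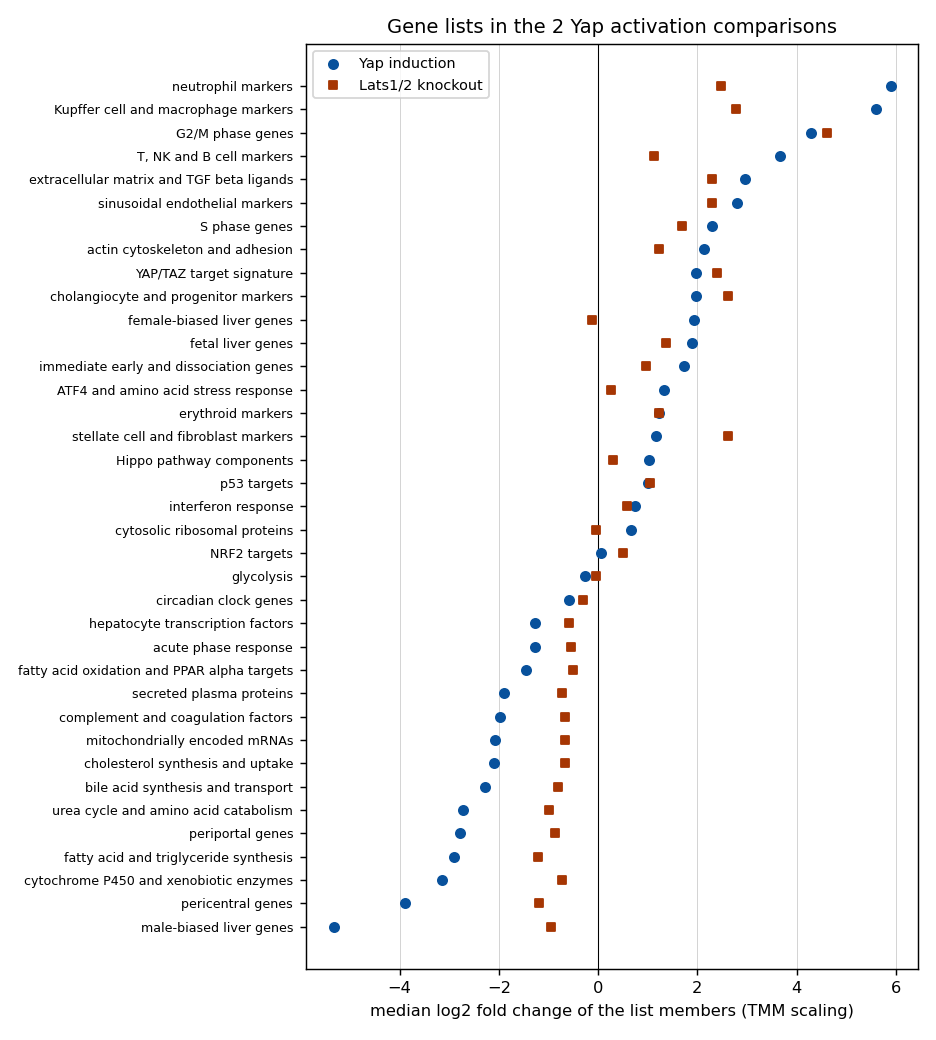
Median log2 fold change of the measured members of each of 37 gene lists on the TMM scale, for Yap induction (circles) and the Lats1/2 knockout (squares). G2/M phase genes have medians of 4.30 and 4.62, and genes of the urea cycle and amino acid catabolism −2.72 and −0.998.

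Whether the knockout and the transgene changed the same genes was tested with separate controls. Of the 2668 genes higher in the knockout 2366 (88.7%) were also higher after Yap induction, where independent lists would share 933.1, and of the 2258 lower genes 1989 (88.1%) were shared against 722.1. In 54 genes the calls went opposite ways. Across the 12970 genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.82 and Spearman rho = 0.81. Net of doxycycline and of the virus, the comparisons share the BL/6 controls, and gave 1438 genes higher and 1194 lower in both, against 449.8 and 406.2 for independent lists, with r = 0.77 and a covariance of 2.88. Simulated unchanged groups gave r = 0.25 and a covariance of 0.11. Macrophage and endothelial markers rose in both comparisons, by medians of 5.61 and 2.81 after Yap induction and 2.78 and 2.29 in the knockout. The shared calls and the correlation are not separated from this common rise of RNA of other cells. They are thus not assigned to hepatocytes alone.

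**Figure D5:**
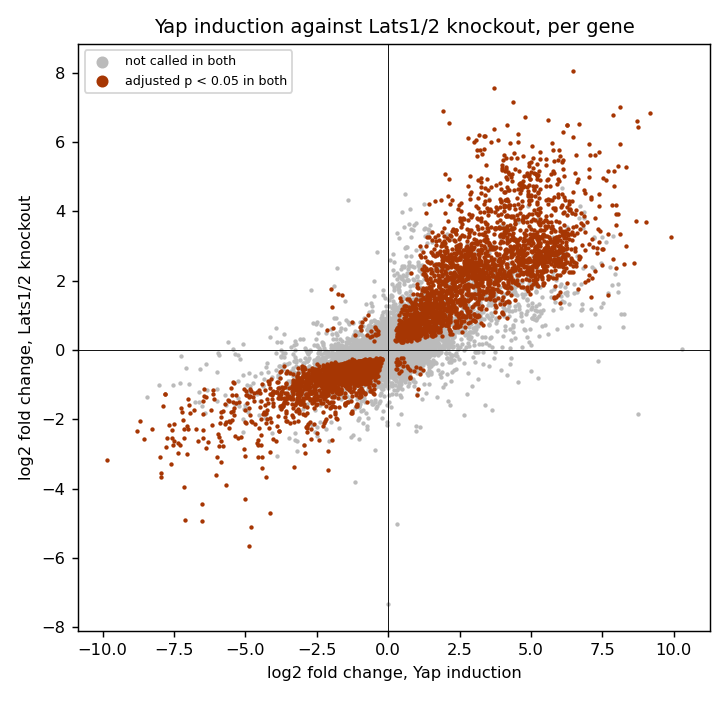
Log2 fold change per gene on the TMM scale after Yap induction (x axis) and in the Lats1/2 knockout (y axis) for 12970 genes, with those past an adjusted p of 0.05 in both coloured. Pearson r was 0.82 and 54 genes were called in opposite directions.

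The difference between the 2 responses was tested gene by gene as an interaction. Hepatocyte genes fell less in the knockout than after Yap induction: 34 of 38 genes of the urea cycle and amino acid catabolism had a higher log2 fold change in the knockout (35 adjusted over the list alone), with a median difference of 1.63 (camera adjusted p = 4.1e-26; 0.029 with an estimated correlation). The same held for 26 of 30 complement and coagulation factors (27; median 1.48), 24 of 25 secreted plasma proteins (24; 1.15) and 25 of 30 cytochrome P450 and xenobiotic enzymes (26; 2.41). Their adjusted p was 2.5e-24, 4.1e-16 and 2.4e-20, and 0.028, 0.037 and 0.029 with an estimated correlation. Slc10a1 differed by 3.67 (SE 0.37), F7 by 2.54, Abcb11 by 2.20, Ttr by 2.09 and Arg1 by 1.79. Macrophage markers were lower in the knockout in 20 of 21 cases (20), with a median difference of −2.88 (adjusted p = 8.2e-11; adjusted p = 0.24 with an estimated correlation), and so were 35 of 40 ribosomal protein genes (38), with a median of −0.71 (adjusted p = 3.0e-12; adjusted p = 0.12 with an estimated correlation). G2/M phase genes (1 of 37 called, median 0.10 or −0.33 with total counts alone, adjusted p = 0.75), S phase genes (0 higher and 3 lower, −0.41, 0.13) and YAP/TAZ targets (3 higher and 4 lower of 20, −0.60, 0.15) were not called as lists, with 0, 1 and 7 called adjusted over the list alone. The counts in brackets are adjusted over the list alone.

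By the fixed rule the largest differences were those of Dct (7.09), Cyp2c40 (7.02) and Hsd3b5 (6.66) upward, and Apela (−10.25), Mmp9 (−6.09) and Pla2g7 (−5.57) downward. Macrophage markers had a median difference of −2.88, so those of Mmp9 and Pla2g7 are not assigned to hepatocytes. Dct had 3 counts in ApoYap Dox and 364 in its controls, a ratio of 187.2 with a 95% counting interval of 63.6 to 912.2. In all, 2261 genes were higher and 1602 lower in the knockout than after Yap induction (2257 and 1578 without marker genes). With total counts alone, which lowered the median of all genes by 0.45, these were 1174 and 3653, 24.3% higher instead of 58.5%. The fitted log2 value of Apela depends on a control with 1 count and is no bound.

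Doxycycline alone, the control for side effects of the inducer and its sucrose, changed few genes in BL/6 mice. Arntl, a core clock transcription factor, fell by 1.57 (SE 0.25, adjusted p = 0.0054), from 8.67 ± 0.56 CPM (n = 4) to 2.95 ± 1.12 CPM (SD, n = 4). Dusp1, a phosphatase induced by stress, fell by 1.62 (SE 0.30, adjusted p = 0.023) and Sik1, a kinase induced by cAMP, by 1.48 (SE 0.28, adjusted p = 0.022). The 3 genes higher were Klf13 (0.91, SE 0.17), Atm (0.80, SE 0.16) and Herc1 (0.63, SE 0.13), with adjusted p of 0.020, 0.030 and 0.049. The test called 3 genes higher and 13 lower, with 1543 genes at an unadjusted p under 0.05. DESeq2 called 51 and 61 and limma voom 45 and 54, and each named call except that of Arntl was lost on leaving out at least 1 library. Without BL/6 Dox 4 the adjusted p was 0.12 for Klf13, 0.13 for Atm, 0.13 for Herc1, 0.12 for Dusp1 and 0.12 for Sik1. The counts higher and lower were 1 and 8 without BL/6 ctrl 1, 0 and 6 without BL/6 ctrl 2, 9 and 23 without BL/6 Dox 1, 1 and 8 without BL/6 Dox 3, and 0 and 4 without BL/6 Dox 4, and 1 gene was higher without BL/6 ctrl 3.

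As lists, 2 were higher and 11 lower with doxycycline alone under the preset correlation, and none with an estimated one. Immediate early and dissociation genes had a median of −0.68 (1 of 28 called, 6 adjusted over the list alone, camera adjusted p = 2.5e-08; adjusted p = 0.605 with an estimated correlation). Stellate cell markers had a median of −0.98 (adjusted p = 8.4e-08; adjusted p = 0.605 with an estimated correlation) and G2/M phase genes one of −0.65 (adjusted p = 6.9e-05; adjusted p = 0.65 with an estimated correlation), with 0 members called in either adjustment. YAP/TAZ targets had a median of −0.46 and 0 of 20 called in either adjustment (adjusted p = 0.0042; adjusted p = 0.605 with an estimated correlation). Endothelial and macrophage markers had medians of −0.53 and −0.39, with 0 called in either adjustment (camera adjusted p = 5.1e-06 and 0.011, or 0.605 and 0.77 with an estimated correlation). In BL/6 Dox 1 their sums were 65.5 and 66.7 unscaled CPM, the lowest of all 25 libraries, so a change of these lists is not separated from a smaller share of other cells. Of the BL/6 Dox libraries, 1 and 2 lay apart in the principal components; without both, a choice made after the data were seen, 30 genes were higher and 44 lower. The 2 libraries left stand in columns 24 and 25 of the table and all BL/6 ctrl libraries in columns 1 to 10, so these numbers are confounded with the column order.

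The virus alone, by its protocol 24 hours after injection, was followed by a rise of p53 targets. Cdkn1a, the cell cycle inhibitor p21, went from 20.3 ± 5.11 CPM (n = 4) to 198.9 ± 74.3 CPM (SD, n = 3), a log2 fold change of 3.29 (SE 0.49, adjusted p = 0.0074). Ccng1 rose by 1.09 (SE 0.15, adjusted p = 0.0018) and Trp53inp1 by 1.66 (SE 0.34, adjusted p = 0.039). These were the 3 of 22 p53 targets called, and 9 were higher adjusted over the list alone, with a median of 0.82 (camera adjusted p = 1.4e-11; 0.0077 with an estimated correlation). Noct, a gene under clock control, rose by 2.28 and Gbp3, an interferon-induced GTPase, by 2.13. Bmp4 (−2.02), Incenp (−1.64) and Rnf125 (−1.16) fell. Interferon response genes had a median of 0.75 (1 of 34 higher, 10 adjusted over the list alone, adjusted p = 7.5e-11; adjusted p = 0.61 with an estimated correlation). Acute phase genes had a median of 0.67 (0 of 29 called, 14 adjusted over the list alone, adjusted p = 1.2e-08; adjusted p = 0.61 with an estimated correlation). Ribosomal protein genes had a median of −0.21 and G2/M phase genes one of −0.87, with 0 called in either adjustment (adjusted p = 7.7e-09 and 1.8e-07; adjusted p = 0.61 and 0.64 with an estimated correlation). Stellate cell markers had a median of −0.59 (0 of 20 called in either adjustment, camera adjusted p = 0.0080, or 0.80 with an estimated correlation). Mitochondrial mRNAs had a median of −0.27 (0 of 8 called, 2 adjusted over the list alone, camera adjusted p = 0.0070, or 0.61 with an estimated correlation). They went from 14.95 ± 0.46% to 11.5 ± 1.30% of counts, so these negative list medians are not separated from a change in the composition of the samples.

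In number, 33 genes were higher and 6 lower with the virus alone, with 1720 at an unadjusted p under 0.05. The count rests on the model and on single libraries: with only the 2 compared groups in the fit it was 274 and 218, and without BL/6 AAV-Cre 1 it was 100 and 22. Without BL/6 ctrl 1, 2, 3 and 4 the numbers higher were 6, 17, 8 and 21, and without BL/6 AAV-Cre 2 and 3 they were 15 and 6. The numbers lower were 3 without BL/6 ctrl 1, 3 without BL/6 ctrl 3, 2 without BL/6 AAV-Cre 2 and 1 without BL/6 AAV-Cre 3. The calls of Cdkn1a and Ccng1 held without any 1 library, while that of each other gene named for this comparison was lost without at least 1 (Noct without BL/6 ctrl 1, adjusted p = 0.055, and Bmp4 without BL/6 AAV-Cre 3, 0.096). The protocols of the labels give 24 hours for the BL/6 mice and 1 week for the floxed mice. This was not checked against another source, and if it is right, the times differ and the values net of the virus mix time with genotype. The BL/6 AAV-Cre and Lats1/2 flox ctrl columns stand in another part of the table than BL/6 ctrl, and the BL/6 Dox libraries stand in columns 6, 13, 24 and 25 of the table, so a batch that follows this order is confounded with the first 2 groups and in part with doxycycline.

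Net of doxycycline, the response to Yap induction had 3466 genes higher and 3550 lower (3401 and 3549 without marker genes; 7488 and 1420, or 84.1% higher instead of 49.4%, with total counts alone). Under the fixed rule Apela, Cx3cr1 (8.76), a chemokine receptor of myeloid cells, and Lrtm2 (8.68) rose most and Hsd3b5 (−8.82), Cyp4a14 (−8.63) and Mup2 (−8.50) fell most. YAP/TAZ targets rose in 15 of 20 cases (15 adjusted over the list alone; median 2.38, camera adjusted p = 1.3e-06; 0.039 with an estimated correlation) and the urea cycle list fell in 38 of 38 (38; −2.88, adjusted p = 1.3e-30; 0.026 with an estimated correlation). With separate controls, 2 genes were higher and 9 lower both after Yap induction and with doxycycline alone, and 3 went opposite ways. Independent lists would share 1.05 higher and 4.16 lower. The log2 fold changes of these comparisons correlated with r = −0.21 across genes.

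Net of the virus, the knockout had 1683 genes higher and 1484 lower (1630 and 1484 without marker genes; 3487 and 451, or 88.5% higher instead of 53.1%, with total counts alone; 986 lower without Lats1/2 KO 2). Hmmr (7.62), Knl1 and Pbk, all of the mitotic machinery, rose most, and Try5, Saa2 (−8.54) and Saa1 (−7.15) fell most. Knl1 and Pbk had 1 and 2 counts in BL/6 AAV-Cre against 13 and 18 in BL/6 ctrl, ratios of 9.65 (1.45 to 410.3) and 6.68 (1.60 to 59.4), and Try5, a pancreatic trypsin with 1 count in BL/6 ctrl, lost its call without BL/6 AAV-Cre 2 (−3.62, adjusted p = 0.85). G2/M phase genes rose in 35 of 37 cases (36 adjusted over the list alone; median 5.55, camera adjusted p = 8.9e-47; 0.016 with an estimated correlation). Of the lists called in the knockout, p53 targets (median 0.19, adjusted p = 0.96), interferon response genes (−0.13, 0.46), mitochondrial mRNAs (−0.38, 0.13) and NRF2 targets (0.31, 0.062) were not called net of the virus. With separate controls, 6 genes were higher and 3 lower both in the knockout and with the virus alone, and 9 went opposite ways. Independent lists would share 6.79 higher and 1.04 lower. The correlation across genes was r = −0.16.

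Doxycycline alone and the virus alone share the BL/6 ctrl libraries. Klf13 and Herc1 were higher in both and no gene was lower in both. The 10 simulations with shared controls gave 0 shared calls. They hold no changed gene, so shared calls were hardly possible there and this 0 decides nothing. Untreated Lats1/2 flox ctrl, in the later part of the table with BL/6 AAV-Cre, had 129.9 CPM of Klf13 and 29.0 of Herc1, against 82.0 and 17.5 in BL/6 ctrl, which goes with column order. BL/6 Dox 1, in column 6, had 124.2 and 24.0 CPM, above every BL/6 ctrl library, which goes with doxycycline. In columns 2 to 12 both genes were also higher in ApoYap Dox than in ApoYap ctrl (157.7 against 87.1 CPM and 33.5 against 19.8). That pair differs by YAP induction as well as by doxycycline. The correlation of log2 fold changes was 0.50 and the covariance 0.24, against a mean of 0.46 and 0.11 for simulated unchanged groups. With the controls split between the comparisons, r was 0.13 to 0.22 and the covariance 0.086 to 0.14; 0 genes were then shared, but only 2 to 13 and 0 to 4 were called, too few to decide.

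The untreated strains were compared as a scale for these effects. ApoYap ctrl had 19 genes higher and 38 lower than BL/6 ctrl (30 and 36, or 45.5% higher instead of 33.3%, with total counts alone). Lats1/2 flox ctrl had 409 higher and 126 lower (273 and 188, or 59.2% instead of 76.4%), and 173 and 36 without BL/6 ctrl 4. In the first comparison the lowest numbers were 10 higher without BL/6 ctrl 4 and 22 lower without ApoYap ctrl 3. Cdkn1a was higher in Lats1/2 flox ctrl by 1.98 (SE 0.46, adjusted p = 0.018), at 80.3 ± 71.6 CPM and between 36.3 and 187.4.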

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

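The tests of the macrophage markers and of the p53 targets, those of scaling and of dilution for the hepatocyte genes, and the split that exchanges the lines were chosen only after the result was seen.

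Macrophage markers rose with Yap induction by a median of 5.61, although hepatocytes were sorted, and abundant macrophage genes rose together: C1qb from 22.5 to 1173 CPM, Ctss from 17.7 to 1086 and Lyz2 from 17.4 to 994.7. A lower hepatocyte share that raises all other cell types alike is argued against, since the medians of the macrophage and stellate cell lists differed by 4.43. A scaling factor moves both lists alike and so does not give this difference. The permutation p of 1e-05, the smallest these permutations can give, exchanges genes that are not independent and measures no spread between libraries. By library, macrophage sums were 14760 to 26633 unscaled CPM in ApoYap Dox against 113.2 to 266.7 in ApoYap ctrl. Stellate sums were 345.1 to 585.2 against 71.8 to 162.6. The endothelial median, 2.81, lay between and the neutrophil median was 5.90, so the gap depends on the list chosen. Whether the macrophage RNA comes from more macrophages in the liver, from cells bound to hepatocytes through the sort, or from expression in hepatocytes was not tested.

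p53 targets rose after the virus in BL/6 mice, by the protocol at 24 hours, by a median of 0.82, but BL/6 AAV-Cre and BL/6 ctrl stand in different parts of the table. A batch that follows this order may account for part of it: Cdkn1a was higher by 1.98 in the untreated Lats1/2 flox ctrl than in BL/6 ctrl (adjusted p = 0.018), although with a wide spread (80.3 ± 71.6 CPM, SD, from 36.3 to 187.4), and AAV-Cre exceeded Lats1/2 flox ctrl by 1.31, which was not called (adjusted p = 0.47). BL/6 Dox 2, 3 and 4 stand in the same later part and are of the same strain as BL/6 ctrl, and against BL/6 ctrl their p53 median was −0.0046 (SE 0.11) and Cdkn1a −1.23 (adjusted p = 0.34), so they did not share the rise. AAV-Cre exceeded these 3 libraries by a median of 0.68 (SE 0.26, 22 genes), or 0.51 (SE 0.26) with BL/6 Dox 3 and 4 alone, which is within 2 SE of 0, and Cdkn1a by 4.52 (SE 0.60, adjusted p = 0.0014), or 4.35 (0.021). For the list these medians go against a batch as the whole cause but do not exclude it. Each SE of a list median, here and in the next paragraph, is over the genes of the list. These are not independent, so it measures no spread between libraries. Against Lats1/2 flox ctrl, in the same part of the table, the p53 list was also higher in AAV-Cre, by a median of 0.44 (SE 0.14), with 2 of 22 genes called. That comparison also crosses strains, and the one within BL/6 crosses treatments. A response to the virus or to Cre remains open.

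Hepatocyte genes fell more with Yap induction than in the knockout, by a median of 1.63 for the urea cycle list. A weak Lats1/2 KO 3 library is argued against, since the median was 1.47 without it (SE 0.13), and scaling is argued against by a median of 1.18 with total counts alone (SE 0.13). Dilution by RNA of other cells is argued against as the whole cause, since the urea cycle list fell further than Alb in Yap induction by a median of −1.81 (SE 0.17), although Alb is a single gene. A stronger or earlier activation of YAP by the transgene than by deletion could give this difference and was not tested, and neither was the difference of strain.

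For 17 of 29 genes named for both, the log2 change differed between the knockout and Yap induction at an adjusted p under 0.05 (edgeR). Many of these genes were named for a large change or a small p in these same data, so this share is no rate of difference. Over all genes it was 3863 of 12970 (29.8%). The differences were 0.72 for Yap1, −1.26 for Lats1, −1.63 for Lats2, −2.33 for Gpc3, 4.41 for Mup15, 4.27 for Mup17, 1.94 for Ajuba, −1.76 for Scd2, −2.16 for Spp1, 1.34 for Sox9, 1.79 for Arg1, 2.09 for Ttr, 2.54 for F7, 2.20 for Abcb11, 3.67 for Slc10a1, 2.70 for Fasn and −2.62 for Cd68.

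In 6 of 76 groups of 4 libraries the gap from 1 library to the next made up most of the range, where chance gives about 1 in 20. Such a gap can be small in itself. Yap1 was at 46.9 CPM in ApoYap ctrl 4 against 40.97 to 41.9 in the others, and Lats2 at 13.7 CPM in Lats1/2 flox ctrl 3 against 12.9 to 13.1. Ankrd1 had 0 CPM in Lats1/2 flox ctrl 4 against 0.33 to 0.36. That Lats2 value is 115 counts and those of Ankrd1 are 0 against 3 counts, so counting error can give both gaps. T, NK and B cell markers were at 9.12 unscaled CPM in Lats1/2 flox ctrl 1 against 2.08 to 3.27, and erythroid markers at 17.3 unscaled CPM in BL/6 Dox 3 against 3.21 to 5.43. The total of BL/6 ctrl 1 was 14.3 M (14317362 counts) against 9522508 to 9819786 counts.

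Other splits of the libraries gave fewer genes than the real groups in most comparisons. This argues against chance there but does not exclude it, since the best possible share is 1 of 35 and several comparisons were made. Of 35 splits only the real 1 gave as many genes for Yap induction (8684, highest other 6541), the knockout (4926, 3107), doxycycline alone (16, 1), AAV-Cre alone (39, 7), ApoYap ctrl against BL/6 ctrl (57, 1) and Lats1/2 flox ctrl against BL/6 ctrl (535, 12). Of 50 splits only the real 1 did so net of doxycycline (7016, 6662) and net of AAV-Cre (3167, 2411). These splits also mix treated with control libraries, so they do not test whether the responses differ. For the knockout minus Yap induction 5 of 50 splits of treated and control libraries gave as many (3863, 6904), so by these splits chance is not excluded for that count; such splits part treated from control libraries and call genes of either treatment. Exchanging the lines within treated and within control libraries, 2 of 50 did (3863, 4432).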

How the results depend on the processing

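The alternatives that leave out BL/6 Dox 1 and 2 together and that count without marker genes were chosen after the data were seen.

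RLE scaling kept 32 of 32 counts and correlations within 1.5 times, and leaving the 50 most abundant genes out of the scaling 18 of 18. The replicate block moved 1 of 36, genes higher with doxycycline alone (1), kept 253 of 259 gene list results and lost the named calls of Atm (adjusted p = 0.051), Herc1 (0.078), Dusp1 (0.051), Gbp3 (0.076), Rnf125 (0.058) and Try5 (0.094); its numbers do not pair the libraries, since the changes of treated and control libraries with the same number correlated at −0.24 to 0.16. Of 1170 values of named genes without 1 library 1088 kept direction and call and 72 lost the call. With only the compared groups in the fit, the knockout calls of Yap1, Sox9, Alb, Mup15, Mup17, Cyp4a14 and Saa1 were lost (adjusted p = 0.083, 0.058, 0.055, 0.073, 0.12, 0.091 and 0.053), as were those of Klf13, Atm, Herc1 and Dusp1 with doxycycline alone (0.11, 0.14, 0.21 and 0.19), Trp53inp1 with AAV-Cre alone (0.090) and Try5 net of AAV-Cre (0.094), 13 in all, and with voom that of Cyp4a14 (0.13). Yap1 in the knockout was also lost with RLE scaling (0.069), DESeq2 (0.071) and no filter (0.082). Without a filter the calls of Atm (0.053), Dusp1 (0.061), Herc1 (0.061), Gbp3 (0.081), Rnf125 (0.081), Trp53inp1 (0.081) and Try5 (0.068) were lost too, with total counts alone those of Herc1 (0.081) and Gbp3 (0.063), with voom those of Sik1 (0.067), Try5 (0.29) and Cyp4a14 net of doxycycline (0.055), and without BL/6 Dox 1 and 2 those of Dusp1 (0.12) and Sik1 (0.056). The cause was not tested.

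With total counts alone the numbers higher and lower were 8613 and 1638 for Yap induction, 5781 and 572 for the knockout, 7488 and 1420 net of doxycycline, 3487 and 451 net of AAV-Cre and 1174 and 3653 for the knockout minus Yap induction, and 30 were higher in ApoYap ctrl than in BL/6 ctrl. The lists higher were 9 for Yap induction and 10 net of doxycycline, and 3 were lower in the knockout minus Yap induction. With Yap induction Lats1 turned to 0.50 (adjusted p = 0.045), Sox9 to 0.84 (0.018) and Alb to 0.00087 (1.00), and Yap1 in the knockout turned to 0.14 (0.33). By construction this scaling moves all genes of a contrast by 1 value.

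Against a fold of 1.5, a stricter test, the numbers were 2662 lower for Yap induction, 1741 higher and 484 lower for the knockout, 0 and 1 for doxycycline alone, 0 and 0 for AAV-Cre alone, 2352 lower net of doxycycline, 1016 and 406 net of AAV-Cre, 1087 and 699 for the knockout minus Yap induction, 6 and 16 for ApoYap ctrl against BL/6 ctrl and 3 and 4 for Lats1/2 flox ctrl against BL/6 ctrl. At an adjusted p under 0.01, 1383 were lower for the knockout, 0 higher and 4 lower for doxycycline alone, 8 and 2 for AAV-Cre alone, 897 and 761 net of AAV-Cre, 844 lower for the knockout minus Yap induction, 9 and 23 for ApoYap ctrl and 128 and 23 for Lats1/2 flox ctrl. With a log2 fold change of at least 1, 2396 were lower for Yap induction, 541 lower for the knockout, 0 higher for doxycycline alone, 12 higher for AAV-Cre alone, 2335 lower net of doxycycline, 619 lower net of AAV-Cre, 1330 higher for the knockout minus Yap induction and 90 and 32 for Lats1/2 flox ctrl. These thresholds are stricter by construction. Without a filter 1 gene was higher with doxycycline alone, and with the stricter filter, which tests fewer genes, 6 were, and 55 with AAV-Cre alone.

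DESeq2 gave 51 higher and 61 lower for doxycycline alone, 130 and 39 for AAV-Cre alone, 41 and 69 for ApoYap ctrl and 240 lower for Lats1/2 flox ctrl. Limma voom gave 45 and 54, 353 and 212, 66 and 103, and 817 and 382 for these. With only the compared groups in the fit 1449 were lower for the knockout, 274 and 218 called for AAV-Cre alone, 71 and 128 for ApoYap ctrl and 298 lower for Lats1/2 flox ctrl. Without BL/6 Dox 1 and 2, 30 were higher and 44 lower with doxycycline alone. For these alternatives the cause was not tested.

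Genes changed both in Yap induction and in the knockout were 1438 higher and 1194 lower net of the side effects, and 27 opposite; at an adjusted p under 0.01 1268 were lower and 15 opposite, with a log2 fold change of at least 1 474 and 6, and with voom 117 were opposite. For Yap induction with doxycycline alone DESeq2 gave 17 higher, 32 lower and 28 opposite and an adjusted p under 0.01 0, 2 and 0. For the knockout with AAV-Cre alone these were 20, 9 and 44, and 3, 0 and 2, and for doxycycline alone with AAV-Cre alone 12 higher, 2 lower and 1 opposite with DESeq2 and 0 higher at 0.01. The cause was not tested.

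With an estimated correlation camera called 0 lists higher and 7 lower for Yap induction, 3 and 1 for the knockout, 0 and 0 for doxycycline alone, 1 and 0 for AAV-Cre alone, 2 higher net of doxycycline, 2 and 0 net of AAV-Cre and 9 and 0 for the knockout minus Yap induction. Fry called 0 and 0 for doxycycline alone and 1 and 0 for AAV-Cre alone. Estimated correlations above the preset 0.01 widen the test by construction.

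Without 1 library the numbers higher and lower ranged from 4181 to 4408 and 3773 to 4061 for Yap induction, 1948 to 2753 and 1391 to 2358 for the knockout, 0 to 9 and 4 to 23 for doxycycline alone, 6 to 100 and 1 to 22 for AAV-Cre alone, 3160 to 3447 and 3251 to 3601 net of doxycycline, 1161 to 1852 and 986 to 1737 net of AAV-Cre, 1791 to 2335 and 1177 to 1776 for the knockout minus Yap induction, 10 to 14 and 22 to 36 for ApoYap ctrl and 173 to 332 and 36 to 101 for Lats1/2 flox ctrl. The highest numbers for doxycycline alone came without BL/6 Dox 1 and for AAV-Cre alone without BL/6 AAV-Cre 1. Depth limits genes near the floor of 3 counts, 0.11 to 0.42 CPM per library.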
